A study of Mus musculus with 24 samples.

How the data were processed

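Gene expression was measured by RNA sequencing in the apex of the heart of 24 wild-type C57/Bl6J mice. Each mouse had sham surgery or transverse aortic constriction (TAC, a suture that narrows the aorta around a 25-gauge needle and loads the left ventricle with pressure). It was kept in normoxia or hypoxia, and was killed on day 3. The 4 combinations hold 6 mice each. Libraries were made from 100 ng of total RNA with a low-input kit, per the labels' protocols. The labels give no oxygen level, no length of the hypoxia, no sex, no harvest time and no sequencing batch.

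The deposited values are raw counts per gene symbol, one column per library, with no normalization in the file. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0.422, STAR 2.7.3a and featureCounts of Subread 2.0.0 with genome build GRCm39. The notes state no settings, annotation release or strand setting, so reads from overlapping or antisense genes and from near-identical copies (the alpha-globin pair Hba-a1 and Hba-a2, the beta-globin pair Hbb-bs and Hbb-bt) cannot be assigned with certainty. Gene symbols are printed as in the file. Of its 40840 names, 39350 (96.4%) match a RefSeq symbol of build GRCm38, the reference at hand, and no coordinates are printed because the builds differ. Library numbers in the file header were joined to the samples through the sample descriptions.

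Total counts per library ran from 10136915 to 15058159. Of the 40840 genes, 11898 had no count in any library. The filter filterByExpr of edgeR (minimum count 10, minimum total 15) kept 15027 genes, which hold 99.9% of all counts. The biological coefficient of variation was 0.241 over all libraries. Counts of PCR-amplified reads carry counting error and amplification error, and the tests below rest on the spread between mice.

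Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3, by the robust quasi-likelihood F test with 1 mean per group in 1 model of all 24 libraries, which leaves 20 residual degrees of freedom. The contrasts were TAC against sham in normoxia and in hypoxia, hypoxia against normoxia after sham surgery, hypoxia against normoxia after TAC, and the difference between both TAC responses (the interaction). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Values after ± are standard errors for log2 changes and standard deviations for CPM and scores. CPM are TMM-scaled, and log2 CPM used a prior count of 2.

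Gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The 30 lists cover cells, stress, metabolism and signalling. They are hypertrophy and cardiac stress genes, adult cardiomyocyte contraction and calcium handling, extracellular matrix and fibrosis, resident fibroblast markers, macrophage and monocyte markers, neutrophil markers, lymphocyte markers, and endothelial markers. Further ones are pericyte and smooth muscle markers, erythroid cell markers, adipocyte markers, mesothelial markers, atrial myocyte markers, skeletal muscle markers, and HIF target genes. Others are glycolysis, fatty acid oxidation and PPAR-alpha targets, oxidative phosphorylation, cell division, inflammatory cytokines with chemokines and adhesion molecules, interferon-stimulated genes, amino acid response and integrated stress response, and endoplasmic reticulum chaperones. The rest are angiogenesis, NRF2 and antioxidant genes, immediate-early genes, circadian clock, glucocorticoid response, ribosome biogenesis, and sex-linked genes. The 27 lists with 2 or more tested members were tested with fry of limma 3.58.1 on voom values, adjusted over lists within a contrast. The directional p of fry asks whether members move one way on balance, and does not compare a list with other genes. Members called were counted over all genes tested and adjusted over the list alone. Camera with a preset correlation of 0.01 and with an estimated correlation were alternatives. Some genes sit in more than 1 list, such as Per1 (clock and glucocorticoid), Mt1 and Mt2 (antioxidant and glucocorticoid) and Pdk4 (fatty acid and glucocorticoid).

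The rule for named genes took, per contrast, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM and a symbol that is not a predicted or clone name, up to 4 members of each list with the smallest p, and a panel of 22 genes. The text names part of these genes, and some are not reported here. The size of the TAC response was scored per mouse as the mean log2 CPM of the genes raised minus that of the genes lowered by the mean TAC effect of both oxygen conditions (adjusted p under 0.05 and at least a 2-fold change, 640 and 159 genes). The difference between both responses was tested by the exact two-sided permutation of oxygen labels within each surgery. Overlaps of calls are given beside the number that independent lists would share.

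Alternatives fixed in advance were median-of-ratios scaling (RLE), the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, no low-count filter, a minimum change of 2-fold, erythroid genes left out, the replicate number as a block, a fit of only the 12 libraries of a comparison, and each library left out in turn. After the data were seen, limma-voom with 1 variance factor per group, fits without the 2 libraries with a TMM factor under 0.9 (normoxia TAC 4 and hypoxia TAC 6), and fry on the 12 libraries of a comparison were added.

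The tests were tested on simulated data with the means and library sizes of these libraries and 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. With equal spread, edgeR on all 24 libraries recovered 28.4%, 73.1% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold between the sham groups. TAC mice differed more from each other than sham mice, so the simulation was repeated with TAC and sham libraries given their own spread. The fit of all 24 libraries then made 132 false calls between the TAC groups, 48.5% of its calls, against 8 (7.92%) in the fit of those 12 libraries. Between the sham groups it recovered 20.9% of the 1.5-fold changes, against 62.7% in the fit of those 12 libraries. For this reason counts from the 12 libraries stand beside both comparisons of hypoxia with normoxia. In that simulation fry found the 1 list changed by 1.5-fold in every contrast, and also called 6 of 26 unchanged lists for TAC in normoxia, 3 for TAC in hypoxia and 1 for hypoxia after TAC, so calls of lists in these contrasts are less certain than their p.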

Results

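Transcripts were counted in the heart apex of 24 mice, 6 per group, 3 days after aortic constriction (TAC) or sham surgery in normoxia or hypoxia. The design asks how the early response of the heart to pressure overload differs when the animals live in low oxygen. Mean total counts were 13150000 in normoxia sham, 11740000 in normoxia TAC, 10910000 in hypoxia sham and 11740000 in hypoxia TAC mice. The first principal component held 54.5% and the second 12.03% of the variance of the 1000 most variable genes. Mitochondrial rRNA made up 4.72 ± 0.73% of the counts in normoxia TAC mice, against 3.27 ± 0.31% in normoxia sham, 3.29 ± 0.33% in hypoxia sham and 2.95 ± 0.62% in hypoxia TAC mice.

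In normoxia, TAC raised all 15 tested genes of the hypertrophy and cardiac stress list, the same number adjusted over the list alone. The natriuretic peptide gene Nppb went from 42.1 ± 10.3 to 963 ± 878 CPM (log2 change 4.51 ± 0.71, adjusted p = 0.000251), and Nppa rose by 2.49 ± 0.42. Rcan1, a target of calcineurin signalling, rose by 5.38 ± 0.83, Ankrd1 by 2.81 ± 0.54 and Acta1, skeletal alpha-actin, by 1.83 ± 0.40. The fetal myosin gene Myh7 rose by 1.82 ± 0.30 while the adult form Myh6 fell by 0.85 ± 0.12, from 25240 ± 1571 to 14040 ± 2471 CPM. In all, 4114 of 15027 genes changed (2521 higher, 1593 lower), 1125 of them at least 2-fold.

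Large rises with TAC in normoxia were those of the growth factor gene Ereg (8.54 ± 1.58), the macrophage product Chil3 (8.22 ± 1.60) and Sprr1a (7.91 ± 1.94). Others were those of Spp1 or osteopontin (7.78 ± 1.63), the matrix gene Tnc (7.57 ± 1.25), the hyaluronan synthase Has1 (7.34 ± 1.28) and Fos (6.82 ± 1.53). Of 27 extracellular matrix genes 22 rose (25 adjusted over the list alone), among them Postn (3.36 ± 0.45) and Col3a1 (2.06 ± 0.58). Of 16 macrophage and monocyte markers 12 rose (13 adjusted over the list alone), including Cd68 (1.71 ± 0.40) and Ccr2 (3.29 ± 0.73). All 7 tested neutrophil markers rose, S100a8 by 4.13 ± 0.70, and the same number adjusted over the list alone. Of 18 inflammatory cytokine, chemokine and adhesion genes 16 rose (17 adjusted over the list alone), among them Il1rn (6.57 ± 1.04) and Ccl2 (5.58 ± 0.94). Of 25 cell division genes 16 rose (20 adjusted over the list alone), such as Top2a (2.21 ± 0.69), but the list did not pass as a whole (fry adjusted p = 0.121). Of 15 immediate-early genes 9 rose (12 adjusted over the list alone), with a fry adjusted p of 0.0888.

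Genes of fatty acid oxidation fell with TAC in normoxia, 12 of 23 over all genes and 15 adjusted over the list alone (2 rose there). Among them were Hadha (-0.63 ± 0.12), a subunit of the mitochondrial trifunctional protein, and Acsl1 (-0.55 ± 0.13). Endothelial markers fell in 4 of 12 cases (4 adjusted over the list alone), including Tie1 (-0.71 ± 0.12) and Kdr (-0.67 ± 0.21), the receptor for VEGF. Of 15 clock genes 7 fell and 2 rose (9 and 2 adjusted over the list alone), with Ciart, a repressor of the clock, at -2.31 ± 0.24 and Clock at 0.64 ± 0.14. Smaller groups rose as well. These were 6 of 12 endoplasmic reticulum chaperones (7 adjusted over the list alone; Dnajc3 0.74 ± 0.15) and 6 of 12 amino acid response genes (6 adjusted over the list alone; Asns 1.46 ± 0.30), with 1 falling in both counts. They were also 9 of 14 ribosome biogenesis genes (10, with 1 falling, adjusted over the list alone; Myc 4.32 ± 0.87) and 2 of 10 resident fibroblast markers (2 adjusted over the list alone; Mfap5 1.92 ± 0.27). Large falls were those of Chrna2 (-2.69 ± 0.50), Ciart, Ky (-1.99 ± 0.52), Bcl11b (-1.87 ± 0.54) and Prr29 (-1.84 ± 0.30).

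In the fry test on all 24 libraries the adjusted p for TAC in normoxia was 8.62e-06 for the clock, 0.000775 for hypertrophy, 0.00821 for fatty acid oxidation, 0.0120 for neutrophils, and 0.0122 for extracellular matrix and for macrophages. It was 0.0186 for inflammation, 0.0236 for endothelial markers, 0.0265 for chaperones, 0.0332 for the amino acid response, 0.0375 for fibroblasts and 0.0479 for ribosome biogenesis. With an estimated correlation the adjusted p was 0.166 for the clock, 0.461 for hypertrophy, and 0.511 for fatty acid oxidation, neutrophils, matrix, macrophages and inflammation. That adjusted p was 0.525 for endothelial markers, chaperones, the amino acid response and fibroblasts, and 0.540 for ribosome biogenesis, so none of these calls held in that test. In the 12 normoxia libraries alone 2724 genes were called, 2663 of them among the 4114, and fry no longer passed for inflammation or chaperones (adjusted p = 0.0594 each), the amino acid response (0.0943) or ribosome biogenesis (0.160). The 8 largest rises in that fit ran from Tnc (7.57) to Thbs1 (5.76). Ereg, Chil3, Sprr1a, Spp1 and Has1 were not among those 8, so their rises rest on the fit of all 24 libraries. Of the neutrophil markers 4 were tested in these 12 libraries, and all 4 rose.

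In hypoxia, TAC raised Nppa from 329 ± 114 to 1133 ± 845 CPM (log2 change 1.79 ± 0.41, adjusted p = 0.0107), but Nppb passed no threshold (0.87 ± 0.62, adjusted p = 0.363). Matrix genes rose, 13 of 27 over all genes and 19 adjusted over the list alone, with Spp1 at 6.43 ± 1.42, the cross-linking enzyme Lox at 4.19 ± 0.79 and Timp1 at 4.02 ± 0.98. Other large rises were those of Snhg11 (6.38 ± 1.22), the neutrophil gene Il1r2 (5.43), Sprr1a (5.38 ± 1.37), the stress factor Atf3 (5.30 ± 1.28), Chil3 (5.25 ± 1.65) and Cd300lf (4.28 ± 1.21). Of 12 glucocorticoid response genes 10 rose (10 adjusted over the list alone), such as Fkbp5 (2.38 ± 0.43), Per1 (1.86 ± 0.30), Zbtb16 (1.28 ± 0.25) and Sgk1 (1.18 ± 0.26). In all, 1674 genes changed, 971 higher and 703 lower, 507 of them at least 2-fold.

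Clock genes moved the other way than in normoxia, with 4 higher and 1 lower after TAC in hypoxia (5 and 2 adjusted over the list alone), among them Per2 (2.02 ± 0.29), Ciart (1.31 ± 0.25) and, lower, Npas2 (-1.29 ± 0.29). Hypertrophy genes rose in 4 of 15 cases (5 adjusted over the list alone), including Fhl1 (2.58 ± 0.59) and Uchl1 (1.39 ± 0.29). Rises were also called for neutrophil markers in 4 of 7 (5 adjusted over the list alone) and immediate-early genes in 9 of 15 (13 adjusted over the list alone). Others rose among NRF2 and antioxidant genes in 5 of 12 (7 adjusted over the list alone; Hmox1 3.21 ± 0.66), macrophage markers in 2 of 16 (4 adjusted over the list alone) and inflammatory genes in 2 of 18 (6 adjusted over the list alone; Lcn2 3.42 ± 0.73). The B-cell gene Cd79a fell by 2.09 ± 0.53, the only 1 of 5 lymphocyte markers to fall (1 adjusted over the list alone). The angiogenesis list held 3 falls and 1 rise (5 and 2 adjusted over the list alone), with the apelin receptor gene Aplnr at -2.09 ± 0.47, Kdr at -1.02 ± 0.21 and Pgf at 1.78 ± 0.35. The calcium pump gene Atp2a2 (-0.55 ± 0.14) and Ttn (-0.60 ± 0.09) fell, 2 of the 3 contraction genes that did so (1 rose, and 3 and 1 adjusted over the list alone). Large falls were those of Klra9 (-2.48 ± 0.62), Akap5 (-2.47 ± 0.53), Plscr5 (-2.19 ± 0.51), Prdm1 (-2.03 ± 0.41) and the T-cell receptor gene Cd247 (-1.96 ± 0.33).

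The lists that passed fry for TAC in hypoxia were the glucocorticoid response (higher, adjusted p = 0.0074), the clock (higher, 0.0208) and lymphocyte markers (lower, 0.0261). With an estimated correlation each of these had an adjusted p of 0.516. Matrix, hypertrophy and neutrophil lists each had a fry adjusted p of 0.119. In the 12 hypoxia libraries alone 2086 genes were called, 1429 of them among the 1674, and hypertrophy genes rose in 5 of 15 cases (9 adjusted over the list alone). Il1r2, Chil3 and Cd300lf were not among the 8 largest rises there. Neutrophil markers rose there in 1 of 3 tested cases (2 adjusted over the list alone). Lymphocyte markers did not pass fry there (adjusted p = 0.136, 2 members tested), and the clock and the glucocorticoid response did (0.0173 each). So did HIF targets, NRF2 and immediate-early genes (higher) and contraction genes (lower, 0.0285 each). On all 24 libraries the HIF, NRF2, immediate-early and contraction lists did not pass fry (adjusted p = 0.219, 0.0687, 0.0588 and 0.119). With an estimated correlation their adjusted p was 0.576, 0.516, 0.516 and 0.525. Leaving out hypoxia TAC 3 reduced the 1674 calls to 664, and leaving out hypoxia TAC 4 raised them to 2834. Of 21 calls of genes with the largest changes or in the panel 8 ended in at least 1 of the 24 fits without 1 library, those of Il1r2, Sprr1a and Postn without hypoxia TAC 3 (adjusted p up to 0.116), and of Atf3 without hypoxia TAC 6 (0.0610). The others were S100a8, lost in 17 fits, Chil3 in 13, Retnla in 11 and Cd300lf in 4, with an adjusted p of up to 0.195.

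The same genes answered TAC in both oxygen conditions more often than independent lists would, with 400 shared rises (162.9 for independent lists), 229 shared falls (74.5) and 32 genes called in opposite directions. The response score was 2.92 ± 1.65 in normoxia TAC and 2.62 ± 1.10 in hypoxia TAC mice. Hypoxia sham mice lay at 0.28 ± 0.18, normoxia sham mice at 0.00 ± 0.14. The response was 0.58 smaller in hypoxia (difference -0.58), which was within the spread between mice (exact two-sided permutation p = 0.473 over 853776 permutations). Between the TAC groups the score differed by -0.30 (exact two-sided permutation p = 0.712), and hypoxia sham mice scored 0.28 above normoxia sham mice (exact two-sided permutation p = 0.0173). Among normoxia mice the mean absolute deviation of the score was 1.34 in TAC and 0.116 in sham mice (exact permutation p = 0.00216, the smallest that 6 against 6 allow), and among hypoxia mice it was 0.762 and 0.157 (exact permutation p = 0.0606).

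**Figure D1:**
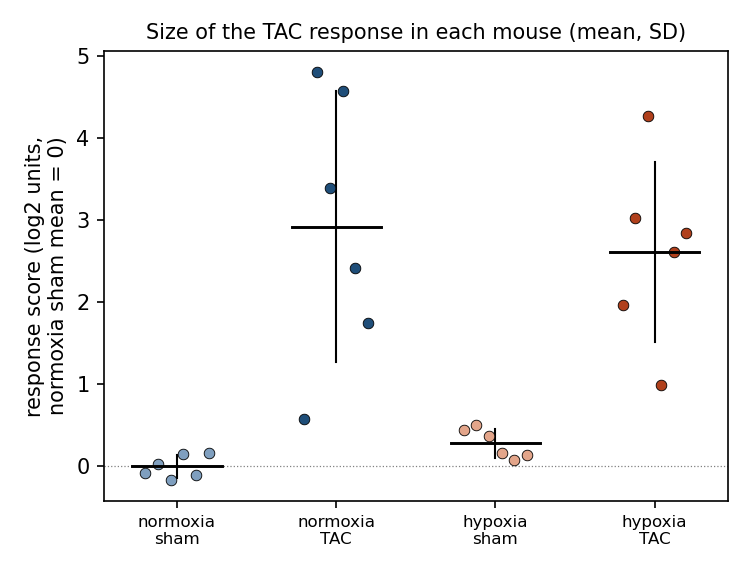
Response score of each mouse in log2 units, with the mean of normoxia sham mice at 0, by group. Points are the 6 mice of a group, horizontal lines the mean and vertical lines the SD. Normoxia TAC mice ranged from 0.58 to 4.81 and hypoxia TAC mice from 0.99 to 4.27, while sham mice stayed between -0.17 and 0.50.

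After sham surgery, genes of the circadian clock were lower in hypoxia than in normoxia mice, with harvest times not given in the labels. Ciart fell from 32.0 ± 14.03 to 4.49 ± 1.04 CPM (log2 change -2.83 ± 0.25, adjusted p = 5.44e-07), Per2 by 1.83 ± 0.28, Per3 by 1.80 ± 0.33 and Tef by 1.29 ± 0.22. Arntl (Bmal1), which drives them, rose by 1.88 ± 0.36 (adjusted p = 0.0291). Other falls were those of the sarcomere gene Tcap (-1.49 ± 0.27), Zbtb16 (-1.20 ± 0.25), Inka2 (-1.11 ± 0.23) and Usp2 (-1.09 ± 0.21). Other rises were those of the protease gene Adam19 (1.98 ± 0.29), Tmem171 (1.80 ± 0.38), Fam124b (1.61 ± 0.32), Ypel2 (1.09 ± 0.19), Fnip2 (1.07 ± 0.17), Srgap1 (0.87 ± 0.18) and Rnf125 (0.79 ± 0.16). In all, 25 genes changed in the fit of all 24 libraries, 13 higher and 12 lower.

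The 12 sham libraries differed little from each other (biological coefficient of variation 0.106), and a fit of these alone called 1658 genes. Of these 947 were higher and 711 lower, 61 and 32 of them at least 2-fold, and all 25 were among them. In that fit Nppb rose by 1.58 ± 0.20 (adjusted p = 0.000944), from 42.1 ± 10.3 to 125 ± 27.7 CPM, Rcan1 by 2.04 ± 0.29 and Postn by 1.25 ± 0.18. Of 15 hypertrophy genes 5 rose and 1 fell (8 and 2 adjusted over the list alone), with a fry adjusted p of 0.00845, against 0.655 on all 24 libraries. Of 24 tested matrix genes 16 rose (17 adjusted over the list alone), and of 16 interferon-stimulated genes 11 (13 adjusted over the list alone; Irf7 0.62 ± 0.08). Among cells that make matrix, 4 of 10 resident fibroblast markers rose (7 adjusted over the list alone; fry adjusted p = 0.00199) and 2 of 10 pericyte and smooth muscle markers (4 adjusted over the list alone; fry adjusted p = 0.00845). On all 24 libraries neither passed (fry adjusted p = 0.239 and 0.225, and 0.359 and 0.339 with an estimated correlation). Rises were called for 7 of 16 macrophage markers (7 adjusted over the list alone) and 6 of 19 glycolysis genes (8 adjusted over the list alone; Ldha 0.45 ± 0.06). Of 24 HIF targets 4 rose and 1 fell (6 and 1 adjusted over the list alone; Egln3 0.97 ± 0.20). Of 12 chaperones 6 rose (6 adjusted over the list alone), and of 8 erythroid genes 3 (5 adjusted over the list alone; Hbb-bs 0.81 ± 0.22). Of 23 fatty acid oxidation genes 16 fell (20 adjusted over the list alone), among them Acot2 (-0.68 ± 0.06) and Fabp3 (-0.36 ± 0.04). Endothelial markers rose in 9 of 12 cases with 1 falling (10 and 1 adjusted over the list alone), such as Vwf (0.95 ± 0.20) and Emcn (0.68 ± 0.07). Of the clock genes 3 rose and 10 fell (3 and 11 adjusted over the list alone). Of 12 glucocorticoid response genes 1 rose and 4 fell (3 and 6 adjusted over the list alone, fry lower, adjusted p = 0.0382). Of 12 NRF2 and antioxidant genes 3 fell (5 adjusted over the list alone, fry lower, adjusted p = 0.0411). On all 24 libraries both had a fry adjusted p of 0.655. In the fit of all 24 libraries the clock had 1 rise and 4 falls (3 and 10 adjusted over the list alone), and endothelial markers had none over all genes and 7 rises adjusted over the list alone. Macrophage, glycolysis, HIF, chaperone and erythroid lists held no call over all genes there (fry adjusted p = 0.655, 0.242, 0.27, 0.655 and 0.546). Most lists passed fry in the 12 sham libraries. Cell division, inflammatory, immediate-early and angiogenesis genes did so too (adjusted p = 0.0159, 0.0251, 0.0287 and 0.0423), but not on all 24 libraries.

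By fry on all 24 libraries the clock (adjusted p = 1.54e-06) and endothelial markers (adjusted p = 0.00225) passed for hypoxia after sham surgery, and both also with an estimated correlation (adjusted p = 8.71e-05 and 0.0142). Matrix (adjusted p = 0.649), fatty acid oxidation (0.0837) and interferon-stimulated genes (0.292) did not pass fry on all 24 libraries, and passed in the 12 sham libraries at 0.00103, 0.000146 and 0.00206. With an estimated correlation on all 24 their adjusted p was 0.711, 0.183 and 0.411. The count depended on single libraries, from 6 without normoxia sham 2 or 3 to 50 without normoxia TAC 2 or 4. Of 16 genes named by size of change 11 lost the call in at least 1 of the 24 fits without 1 library, while Ciart, Per2, Tef, Adam19 and Fnip2 were called in all.

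**Figure D2:**
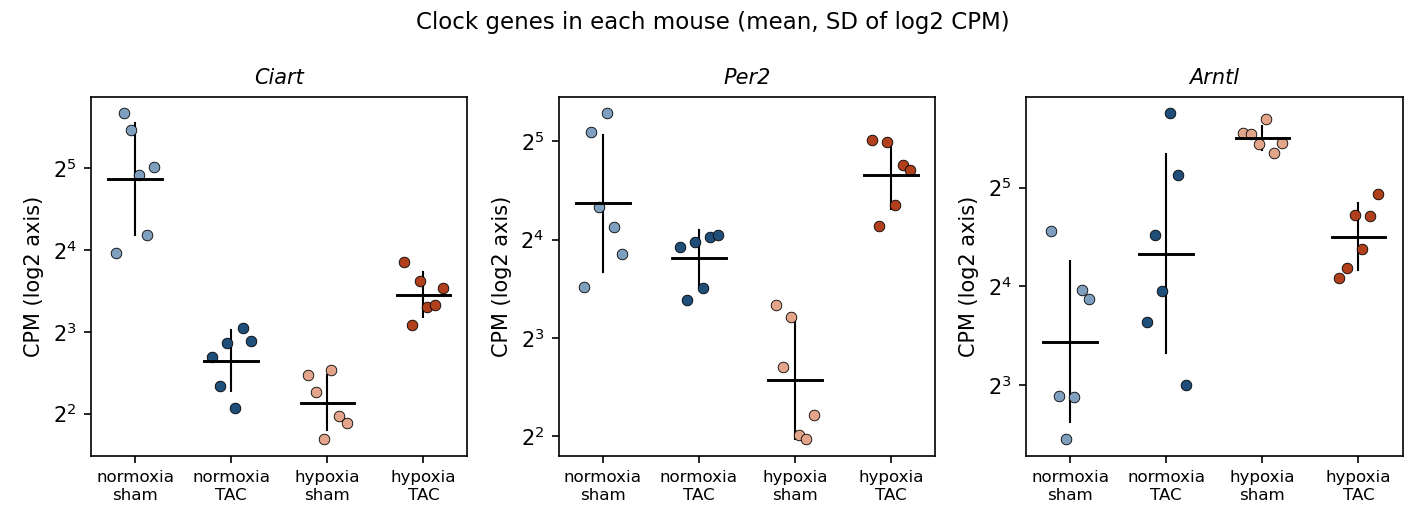
CPM of the clock genes Ciart, Per2 and Arntl in each mouse by group, on a log2 axis. Points are the 6 mice of a group, horizontal lines the mean of log2 CPM and vertical lines its SD. Ciart lay between 15.6 and 51.2 CPM in normoxia sham and between 3.22 and 5.77 CPM in hypoxia sham mice, whereas Arntl lay between 5.47 and 23.6 and between 40.8 and 51.8 CPM.

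After TAC, hypoxia mice had lower Nppb (229 ± 230 against 963 ± 878 CPM, log2 change -2.07 ± 0.64, adjusted p = 0.0386) and Myh7 (-1.28 ± 0.29, adjusted p = 0.00949) than normoxia mice in the fit of all 24 libraries. The red cell anion exchanger Slc4a1 stood at the top of the rises, at 3.54 ± 0.73 (25.4 ± 22.04 against 2.17 ± 3.45 CPM). Next to it rose Trim10 (2.98 ± 0.74), Apol11b (2.85 ± 0.74), Sdk2 (2.50 ± 0.40), AI593442 (2.30 ± 0.45), Tmem179 (2.26 ± 0.46) and Ankrd63 (2.17 ± 0.50). Large falls were those of Alb (-4.36 ± 1.23, at most 11.7 CPM in any normoxia TAC mouse), Il1rn (-2.92 ± 0.75), Gdf15 (-2.76 ± 0.89), and the adhesion gene Sele (-2.73 ± 0.74). Others were those of the monocyte receptor Ccr2 (-2.57 ± 0.70), Ccl2 (-2.47 ± 0.80), Inhba (-2.44 ± 0.68) and Clec7a (-2.25 ± 0.49). In all, 1663 genes changed, 700 higher and 963 lower, 252 of them at least 2-fold.

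Endothelial markers were higher in hypoxia after TAC in 7 of 12 cases (10 adjusted over the list alone), such as Tie1 (0.52 ± 0.12), Eng (0.52 ± 0.12) and Vwf (0.86 ± 0.24), and this was the only list to pass fry (adjusted p = 0.000125). With an estimated correlation its adjusted p was 0.0872. Erythroid markers were higher in 2 of 8 cases (5 adjusted over the list alone; fry adjusted p = 0.0734) and glycolysis genes in 3 of 19 (4 adjusted over the list alone; Pkm 0.39 ± 0.07; 0.0871). Of 14 ribosome biogenesis genes 8 were lower (10 adjusted over the list alone; Nop58 -1.33 ± 0.31; 0.0871). Of 15 hypertrophy genes 6 were lower with none higher (8 lower and 1 higher adjusted over the list alone; 0.129), and of 18 inflammatory genes 4 (11 adjusted over the list alone; 0.504). HIF targets went both ways, with Ddit4 (1.95 ± 0.42, also in the glucocorticoid list) and Ndufa4l2 (0.68 ± 0.15) higher and Tfrc (-1.44 ± 0.41) and Vegfa (-0.69 ± 0.21) lower (2 and 2 adjusted over the list alone). Of 12 glucocorticoid response genes 4 were higher and 1 lower (4 and 1 adjusted over the list alone, fry adjusted p = 0.0933). Of 15 clock genes 3 were higher and 1 lower (4 and 1 adjusted over the list alone, 0.0933). Pericyte and smooth muscle markers were higher in 2 of 10 cases (2 adjusted over the list alone, 0.0871).

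These calls between the TAC groups rest on the spread shared with the sham mice. Of 20 calls of genes with the largest changes or in the panel 11 (Gdf15 in 18 and Ccl2 in 19 of the 24 fits, Nppb in 6) ended without 1 library. In the 12 TAC libraries alone edgeR called 0 genes (2364 at an unadjusted p under 0.05, smallest adjusted p 0.0762, biological coefficient of variation 0.323). Limma-voom with 1 variance factor per group called 98 and DESeq2 on all libraries 2250. In the simulation with unequal spread 24 calls of that voom fit were false (19.4%). DESeq2, run only with equal spread, had 18 false calls (10.8%). Endothelial markers still passed fry in the 12 TAC libraries (adjusted p = 0.00774, with 8 members higher adjusted over the list alone). Hypoxia changed 3 genes upwards after both surgeries (0.606 for independent lists), none downwards (0.769), and 3 in opposite directions, among them Ciart (0.79 ± 0.24 after TAC).

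**Figure D3:**
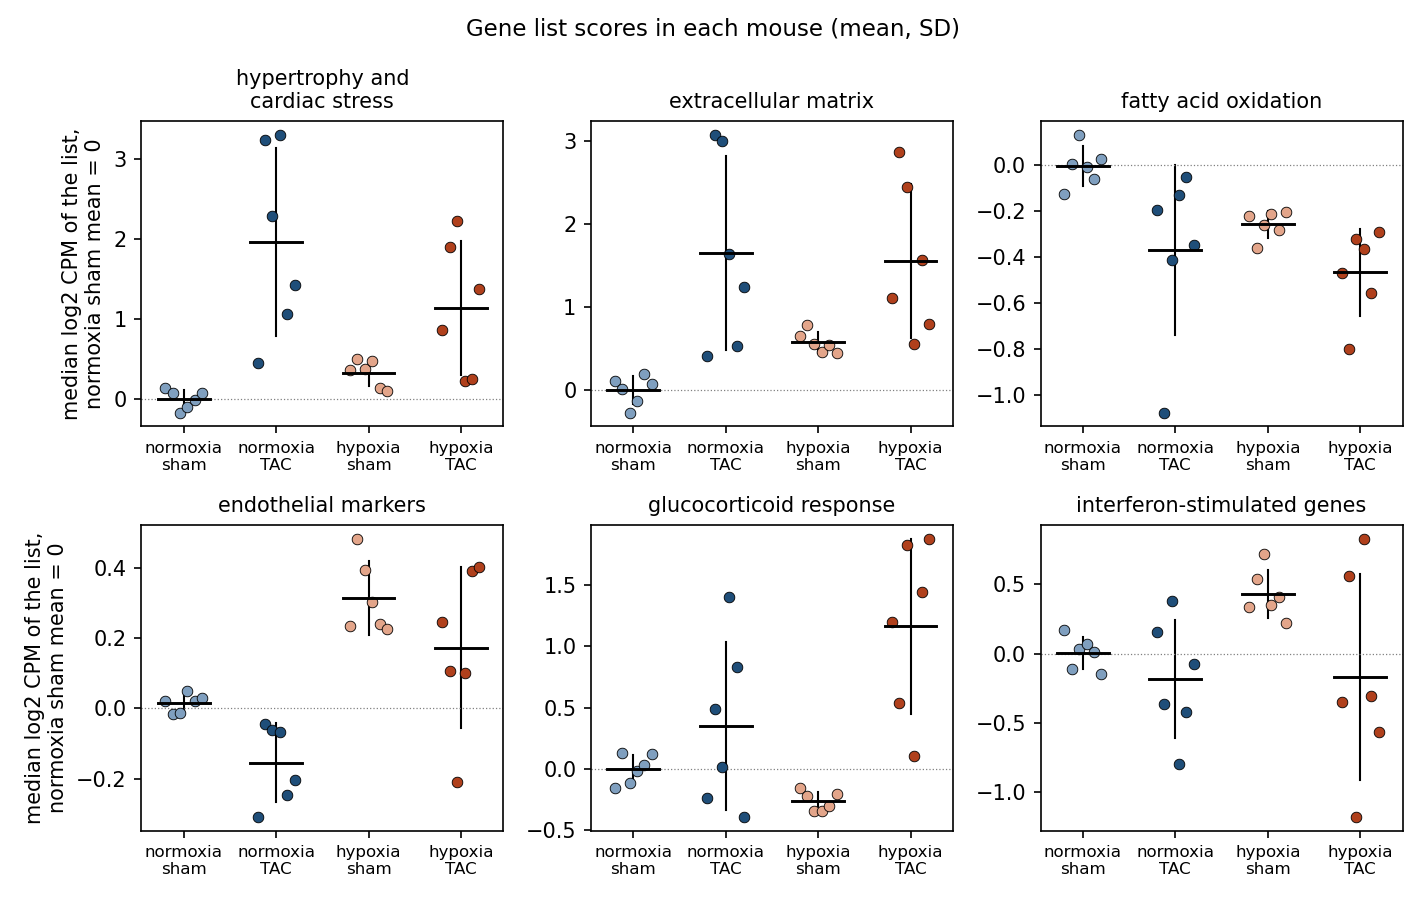
Score of 6 gene lists in each mouse, as the median over members of log2 CPM minus the gene's mean in normoxia sham mice, by group. Points are the 6 mice of a group, horizontal lines the mean and vertical lines the SD. Endothelial markers had a mean of 0.31 ± 0.11 in hypoxia sham mice (0.48 at most), and lay between -0.31 and -0.04 in normoxia TAC mice.

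The response to TAC itself differed between hypoxia and normoxia for 308 genes, with a positive log2 difference (hypoxia minus normoxia) for 169 and a negative one for 139. This balance depended on the fit, with 119 of 300 positive by limma-voom with 1 variance factor per group and 688 of 1529 with sample quality weights. A higher response here means a positive difference, also where a gene fell less or moved the other way in hypoxia. Of the 308 genes, those with a positive log2 change for TAC in normoxia, called or not, changed less in size in hypoxia in 108 cases and more in 33. Those with a negative one changed less in 97 cases and more in 70. Genes that moved the other way in hypoxia are counted here by size alone. Rcan1 (difference -3.99 ± 1.01, adjusted p = 0.0437) and Nppb (-3.65 ± 0.89, adjusted p = 0.0406) rose less in hypoxia. The deiodinase gene Dio2 (-2.78 ± 0.65), B3galt2 (-2.69 ± 0.61), Clec7a (-2.69 ± 0.69), Adam19 (-2.55 ± 0.40), Adgre4 (-2.34 ± 0.51) and Tmem171 (-2.12 ± 0.53) also had lower responses in hypoxia. Adam19 and Tmem171 were already higher in hypoxia sham than in normoxia sham mice (1.98 and 1.80). Between the TAC groups they were not called by edgeR (-0.56, adjusted p = 0.188, and -0.31, adjusted p = 0.619). Higher responses were those of Ankrd63 (3.64 ± 0.70) and the clock genes Ciart (3.62 ± 0.35, adjusted p = 2.65e-06) and Per2 (2.696 ± 0.39). So were those of the HIF family member Hif3a (2.79 ± 0.70), Tmem179 (2.72 ± 0.65), Ppl (2.66 ± 0.52) and Sdk2 (2.59 ± 0.66). Of the 308 genes 230 were called for TAC in normoxia, 103 in hypoxia and 33 in both.

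The clock was the only list whose TAC response differed by fry (adjusted p = 3.05e-06, and 0.00651 with an estimated correlation), with 6 members higher and 2 lower (9 and 3 adjusted over the list alone), such as Per1 (2.30 ± 0.42) and Tef (1.42 ± 0.31). Much of this lay between the sham groups. Hypoxia differed from normoxia in Ciart by -2.83 after sham surgery and 0.79 after TAC, and in Per2 by -1.83 and 0.86. The clock list passed fry between the sham groups (adjusted p = 1.54e-06), not between the TAC groups (0.0933). Unequal harvest times, not given in the labels, cannot be told apart from a changed response to TAC. Of the glucocorticoid response genes 2 had a higher response, Per1 and Zbtb16 (1.59 ± 0.35), and 3 adjusted over the list alone (fry adjusted p = 0.288). Of the hypertrophy genes 2 had a lower response (5 adjusted over the list alone; fry adjusted p = 0.338). Of the fatty acid oxidation genes 2 had a higher one (4 adjusted over the list alone; Slc27a1 1.63 ± 0.35; fry adjusted p = 0.362). The count ranged from 93 without normoxia sham 2 to 946 without hypoxia TAC 2. Of the 16 genes called here that had the largest changes or were in the panel 11 lost the call in at least 1 of the 24 fits that left out a library.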

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

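The tests of clock phase, low oxygen alone, cell mix, loss of Ciart-bearing cells, a graded response, the Nppb level of hypoxia sham mice and the size of the Nppb interaction were chosen after the results were seen.

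The TAC response differed between hypoxia and normoxia, by the interaction test of edgeR, for genes of the naming rule. On the log2 scale, hypoxia minus normoxia, these included Rcan1 (-3.99), Nppb (-3.65), Dio2 (-2.78), B3galt2 (-2.69), Clec7a (-2.69), Adam19 (-2.55), Adgre4 (-2.34), Tmem171 (-2.12), and Flt1 (0.69). Positive differences were also those of Tef (1.42), Zbtb16 (1.59), Slc27a1 (1.63), Per1 (2.30), Sdk2 (2.59), Ppl (2.66), Per2 (2.696), Tmem179 (2.72), Hif3a (2.79), Ciart (3.62) and Ankrd63 (3.64). Among lists the clock differed by fry (adjusted p = 3.05e-06). The larger part of the Ciart difference lay between the sham groups (-2.83, against 0.79 between the TAC groups).

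Clock genes differed between the 4 groups, and in hypoxia sham mice 9 genes of the output arm had a median log2 change of -1.29 and 3 genes of the opposite arm (Arntl among them) one of 1.25. Low oxygen alone is excluded as the whole cause of the differences between the 4 groups, since Ciart also fell with TAC in normoxia (-2.31), but this leaves it open for the shift between the sham groups. Another phase of the clock at harvest is a candidate explanation of that shift, by time of day or by a shifted rhythm, which the labels do not separate because they give no harvest times. The difference between both arms was 2.24 ± 0.78 in normoxia sham, 0.48 ± 1.02 in normoxia TAC, -0.44 ± 0.13 in hypoxia sham and 0.99 ± 0.31 in hypoxia TAC mice (exact two-sided permutation p = 0.00216 for the sham groups, the smallest that 6 against 6 allow). A loss of Ciart-bearing cells of a type with a tested marker list is excluded as the whole cause, since no such list fell in hypoxia sham mice (lowest median 0.036, contraction genes; highest 0.77, erythroid markers), while for cell types without tested markers a changed mix cannot be told apart, as clock levels per cell type were not measured.

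TAC mice of 1 group differed more from each other than sham mice. The libraries with a TMM factor under 0.9 are excluded as the whole cause, since without them the spread in normoxia still differed (exact permutation p = 0.0152). That in hypoxia differed where it had not with all libraries (exact permutation p = 0.0173 against 0.0606). The score genes were still those chosen with all libraries, and normoxia TAC 5 (TMM factor 0.902) was kept, so scaling in general is not excluded. Unequal depth is excluded as the cause, because the SD of the response score in normoxia TAC mice was 12.5 times that of normoxia sham mice after thinning all libraries to the lowest total. A graded response to the constriction may account for the spread, and cannot be told apart with 6 mice per group. Hypertrophy and matrix scores ran together among normoxia TAC mice at Pearson r = 0.777 (exact permutation p = 0.0750; Spearman rho = 0.829, permutation p = 0.0583; r = 0.910 without the 2 farthest) and among hypoxia TAC mice at r = 0.726 (exact permutation p = 0.117; rho = 0.714, permutation p = 0.136; r = -0.210 without the 2 farthest), both with a BH-adjusted permutation p of 0.117 in this family of 2.

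The response of Nppb to TAC was lower in hypoxia (log2 difference -3.65 ± 0.89). With the matrix score as a covariate the difference was -3.30 ± 0.75. This cannot exclude a weaker response of the whole heart, because the matrix score stands for only part of it. The mean matrix score was 1.56 ± 0.93 in hypoxia TAC and 1.65 ± 1.17 in normoxia TAC mice, while the hypertrophy score was 1.14 ± 0.84 and 1.96 ± 1.18. A higher level in sham mice alone would leave the TAC groups alike. Hypoxia TAC mice lay below normoxia TAC mice (log2 difference of means -2.33, unadjusted exact two-sided permutation p = 0.0390), while hypoxia sham mice lay above normoxia sham mice (1.58). In these mice both differences went into the interaction. The test cannot exclude that explanation, because Nppb was flagged for its interaction, which contains the difference between the TAC groups. One library could account for the call by the test fixed beforehand, as 15 of the 24 fits without 1 library ended it, with an adjusted p of up to 0.0736. These were the fits without normoxia sham 1 to 6, normoxia TAC 3 or 4, hypoxia sham 1, 2, 3, 4 or 6, and hypoxia TAC 1 or 6. The size of the difference ran from -4.16 to -3.08 over the 24 fits, so the call lay near the threshold and no single library made up the difference.

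In groups of 6, single mice lay far from the other 5 in 5 of 124 sets of values, where chance gives about 1 in 20 (6.20 sets). The TMM factor of hypoxia TAC 6 was 0.883 (others 1.02 to 1.05). Mki67 stood at 2.56 CPM in normoxia sham 6 (others 1.13 to 1.49), Myh7 at 408 CPM in hypoxia sham 5 (others 250 to 277), Nppb at 23.3 CPM in normoxia sham 4 (others 39.9 to 54.1) and Timp1 at 4.18 CPM in hypoxia sham 1 (others 1.66 to 2.04).

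Chance can be excluded for the counts of genes changed by TAC in normoxia (4114, against at most 2556 in the other splits of the libraries), by TAC in hypoxia (1674, at most 967) and by hypoxia after sham surgery (25, at most 0), where only 1 of 100 splits, the real one, gave as many. For the interaction (308, at most 186) the real split was also the only 1 of 100 to give as many. Its splits exchanged oxygen labels within each surgery, so they cannot tell a differing TAC response from any other effect of oxygen. Chance is therefore not excluded for the interaction itself, and 243 of the 308 genes were also called between the TAC groups. For hypoxia after TAC chance cannot be excluded, since 6 of 100 splits gave at least the real 1663 genes and the highest of the others gave 3617. In 1 set of simulated data with unequal spread, 48.5% of the calls between the TAC groups were false (132 false calls). That share depends on the number of genes changed in the simulation, and does not carry over to the 1663 real calls.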

How the results depend on the processing

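Limma-voom with 1 variance factor per group, fry on 12 libraries and the fits without libraries with a TMM factor under 0.9 were chosen after the data were seen; the other alternatives were fixed beforehand.

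RLE scaling and leaving out erythroid genes kept all 5 counts within 1.5 times. No called gene with one of the largest changes or in the panel, response size or list that passed reversed under any alternative run, while some lists that passed in neither fit changed direction. Genes named only through a list were not part of this check. Counts for TAC in normoxia, TAC in hypoxia, hypoxia after sham surgery, hypoxia after TAC and the interaction were 4114, 1674, 25, 1663 and 308. A 2-fold minimum left 1125, 507, 252 and 134 for all but the sham comparison, and 203 of the 629 genes shared by both TAC responses. Without a low-count filter, which tests more genes, 1019 were called for TAC in hypoxia, 11 for hypoxia after sham surgery, 1031 for hypoxia after TAC and 135 for the interaction. With the replicate number as a block, which the libraries did not bear out (mean correlation 0.00971 for the same number, -0.00174 otherwise), the sham comparison gave 13.

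With 12 libraries edgeR called 2724 genes for TAC in normoxia, 2086 for TAC in hypoxia and 1658 for hypoxia after sham surgery. For hypoxia after TAC it called 0 (2364 at an unadjusted p under 0.05), and DESeq2 on all libraries called 2250. Voom with sample quality weights gave 2871 for TAC in hypoxia, 1643 for hypoxia after sham surgery, 1264 for hypoxia after TAC and 1529 for the interaction. With 1 variance factor per group it gave 2858, 1400, 98 and 300. For the interaction the share of higher responses went from 169 of 308 to 688 of 1529 and 119 of 300 in these 2 fits. DESeq2 gave 96 for hypoxia after sham surgery, 909 for the interaction and 12 genes shared by both hypoxia comparisons (3 with edgeR). In the simulation with equal spread 11.9% and 15.7% of its calls for the first 2 were false, against 2.99% and 9.26% for edgeR on all libraries. Without the 2 low-TMM libraries hypoxia after TAC gave 590 and the interaction 107. Apart from the filter, the 2-fold minimum and fewer samples, the cause was not tested.

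Leaving out 1 library gave 3151 to 5083 for TAC in normoxia. TAC in hypoxia ran from 664 to 2834, with 1105, 927, 845 and 1050 without hypoxia sham 1, 3, 4 and 6 and 664, 2834 and 924 without hypoxia TAC 3, 4 and 5. Hypoxia after TAC ran from 775 to 2169, with 1045 without normoxia TAC 4 and 1031, 775 and 1091 without hypoxia TAC 1, 5 and 6. Hypoxia after sham surgery ran from 6 to 50, with 6, 6, 9, 14 and 12 without normoxia sham 2 to 6, 14, 7, 9, 9, 13 and 10 without hypoxia sham 1 to 6, and 44, 50 and 50 without normoxia TAC 1, 2 and 4. The interaction ran from 93 to 946, with 93, 141, 150 and 132 without normoxia sham 2, 4, 5 and 6, 639, 639, 181 and 684 without normoxia TAC 1, 2, 4 and 5, 148, 143, 113, 105 and 162 without hypoxia sham 1, 2, 3, 4 and 6, and 179, 946, 606, 114 and 170 without hypoxia TAC 1, 2, 4, 5 and 6. The difference in response size ran from -0.99 to -0.12.

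Of 184 results of genes with the largest changes or in the panel DESeq2 kept 177 on their side of the threshold (7 gained), RLE 179 and no filter 153. Calls were lost for 20 with the replicate block, 29 with 1 variance factor per group, 17 with quality weights, 20 with 12 libraries and 23 without the low-TMM libraries, where the last 2 fits cover fewer of these genes. In the same order, these fits gained 2, 9, 15, 11 and 2 calls. Of 135 list results camera with an estimated correlation lost 16 and with a preset one gained 34 and lost 4, and fry on 12 libraries gained 21 and lost 5 of 108. Depth, 10136915 to 15058159 counts, leaves genes such as Il1b (8 counts in all normoxia sham mice) untested.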

Other observations

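All tests of the correlations between list scores were chosen after the scores were seen.

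Some lists and untested genes stand outside the comparisons above. Of the mesothelial markers only Wt1 was tested, and it rose with TAC in hypoxia (0.90 ± 0.21) and was higher in hypoxia after TAC (1.08 ± 0.22), with 14.4 ± 2.22 CPM in hypoxia TAC and 6.15 ± 1.49 CPM in normoxia sham mice. Of the atrial markers only Myl4 was tested, and it rose with TAC in normoxia (0.69 ± 0.16) and hypoxia (0.68 ± 0.16). No adipocyte marker was tested, and Adipoq had 8 to 20 counts per group of 6 mice. Skeletal muscle markers rose with TAC in hypoxia in 2 of 5 cases (2 adjusted over the list alone; fry adjusted p = 0.0588), and oxidative phosphorylation had 2 rises and 1 fall of 25 with TAC in normoxia (1 and 0 adjusted over the list alone; fry adjusted p = 0.942). Pericyte and smooth muscle markers had 4 rises and 2 falls of 10 there (4 and 2 adjusted over the list alone; fry adjusted p = 0.449), and of 5 sex-linked genes 1 rose (1 adjusted over the list alone; fry adjusted p = 0.468). The cytokine gene Il1b, below the count filter, had 196 counts over the 6 normoxia TAC mice, 8 in normoxia sham, 23 in hypoxia sham and 34 in hypoxia TAC mice.

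A hypothesis from the list scores was that glucocorticoid signalling may lower interferon-stimulated and lymphocyte genes in TAC mice. Among the 6 normoxia TAC mice the glucocorticoid score ran against interferon-stimulated genes at Pearson r = -0.854 (exact permutation p = 0.0361; Spearman rho = -0.771, permutation p = 0.103) and against lymphocyte markers at r = -0.907 (p = 0.0125 by exact permutation; rho = -0.886, permutation p = 0.0333). Among the 6 hypoxia TAC mice the values were -0.950 (exact permutation p = 0.00556; rho = -0.886, permutation p = 0.0333) and -0.927 (exact permutation p = 0.0167; rho = -0.829, permutation p = 0.0583). Without the 2 farthest mice r was -0.869, -0.863, -0.692 and -0.477. In this family of 4 the BH-adjusted permutation p were 0.0361, 0.0223, 0.0222 and 0.0223, but these pairs were picked by eye from all pairs of 27 lists. Over all 702 pairs (351 in each TAC group) the adjusted permutation p were 0.343, 0.225, 0.202 and 0.249, with 45, 25, 6 and 13 of 351 pairs as large in size, and none of the 702 passed (BH on exact permutation p, 96 at an unadjusted p under 0.05, smallest adjusted p 0.183). With 6 mice the exact permutation p cannot fall below 0.00139, so hardly any pair could have passed over so many, and these values neither support nor exclude the hypothesis.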
